A study of Mus musculus with 10 samples.

How the data were processed

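Gene expression was measured in 10 cultures of mouse marrow progenitors on Affymetrix Mouse Genome 430 2.0 arrays, as the series' design text states. The samples were grouped by the oncogene in their labels: HoxA9, HoxA9+Meis1 and NUP98-NSD1 with 3 clones each, and MLL-ENL with 1 array. The labels do not say whether the clones came from separate animals, so the p-values may measure technical spread more than spread between animals. The deposited table holds 1 intensity per probe set and array on a linear scale, for 45101 probe sets, and all its value columns belong to samples (0 without one). The software that made the values, and its version, are not given in the sources used here. The values show that the authors or their software scaled each array: after removal of the lowest and highest 2% of probe sets, the mean is 2500.01 to 2500.02 on every array. They were therefore used as deposited, without a further normalization.

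Values were analysed as log2(signal + 32), and folds are folds of signal + 32. A fold written as at least a value sets the dimmer group, whose arrays were all below the filter level, at that level; this was chosen after the data were seen. Probe sets were kept if their signal was above the 40th percentile of all values (369.318) in at least 3 of the 10 arrays. Gene symbols came from the platform's probe annotation, updated through a table of mouse genes by Entrez ID for 34754 probe sets; 204 had an Entrez ID that is not in that table. Of all probe sets, 34945 carry 1 symbol (18193 different symbols), 932 carry several and 9211 have no listed gene, besides 64 control probe sets. Each gene was represented by the probe set with the highest mean log2 value over all arrays among those kept with exactly 1 symbol, which gave 14233 genes, 6413 of them with more than 1 kept probe set. Kept probe sets with several symbols or none (5486) were tested apart. Genome coordinates and probe positions were not used here.

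Groups were compared with limma 3.58.1 in R 4.3.3: a linear model with 4 group means, contrasts and eBayes with an intensity trend, on 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 5 comparisons. The single MLL-ENL array is assumed to vary like the clones of the other groups. Values of probe sets of the Hox-A genes, Meis1, Nsd1 and Nup98 are given with p-values adjusted over all kept probe sets. Of 29 gene lists fixed before the data were examined, 28 were tested and 1 of sex-linked transcripts served as a check of samples. The test was limma's camera with a preset correlation of 0.01, adjusted over 84 tests of the 3 replicated comparisons together, and with an estimated correlation beside it. For MLL-ENL, list medians were placed among 10000 random lists matched on mean expression. The genes of a random list were drawn one by one. A percentile therefore leaves out correlation between list members, and it is not a test over replicates. The correlation, covariance and overlap of differences from HoxA9 were set against 1000 simulations of unchanged groups that share the HoxA9 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

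The genes named were chosen by a rule fixed before the data were examined. For each replicated comparison they are the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, and up to 4 called members of each list with the largest change. For MLL-ENL they are the 8 largest each way outside the range of the other group. Hoxa5, Hoxa7, Hoxa9, Hoxa10, Meis1, Nsd1, Nup98, Flt3, Cd34 and Kit could always be named, as could other members of a list whose count is described. The HoxA9 clone numbers do not mark a shared animal or day in the labels, and were used only in an alternative.

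The fit was tested on simulated data, in which 200 of the 14233 genes were changed, 50 per size. Of changes of 1 on the log2 scale, 54% were found between NUP98-NSD1 and HoxA9, 64% between NUP98-NSD1 and HoxA9+Meis1, 46% between HoxA9+Meis1 and HoxA9, 40% between MLL-ENL and NUP98-NSD1 and 24% between MLL-ENL and HoxA9. Of changes of 3, 80% to 94% were found, with 3 to 10 false calls per comparison. In the data up to 32.4% of genes were called, far more than were changed here, so these rates need not hold there.

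Alternatives fixed before the data were examined were quantile normalization, a shift of arrays to a common median, offsets of 1 and 100, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set tested alone, probe sets with an _x_at, _s_at or _a_at suffix left out, eBayes without a trend or with robust estimation, fits of the compared groups alone or without MLL-ENL, the clone number as a block, fry in place of camera, and leaving out each clone in turn. Ranges of a list's adjusted p over 12 alternatives leave out the estimated correlation. Cyclic loess, and a count of genes with at least 2 called probe sets and none called the other way, were chosen after seeing the data. Other splits of the 6 arrays of each replicated comparison into 3 and 3 were also fitted.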

Results

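RNA from 10 cultures of mouse bone marrow progenitors was measured, 1 culture per array, on Affymetrix Mouse Genome 430 2.0 arrays. Oncogenes had made the progenitors grow without limit, and the cultures were kept in stem cell factor with no GM-CSF. HoxA9 is a homeobox transcription factor and Meis1 a homeobox cofactor that binds DNA with it. NUP98-NSD1 joins a nucleoporin to a histone methyltransferase, and MLL-ENL joins another histone methyltransferase to a transcription elongation factor. There were 3 clones for HoxA9, 3 for HoxA9 with Meis1 (HoxA9+Meis1), 3 for NUP98-NSD1, and 1 array for MLL-ENL. The median signal of an array lay between 440.3 (MLL-ENL) and 660.3 (HoxA9 clone 3). The number of arrays limits the precision.

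By their hybridization controls the arrays fell into 2 sets that follow the groups. These 18 probe sets, which read transcripts added to every sample, averaged 14.01 to 14.13 on the log2 scale in the NUP98-NSD1 and MLL-ENL arrays and 13.18 to 13.42 in the HoxA9 and HoxA9+Meis1 arrays. The highest signal on an array was 225137 to 268316 in the first set and 138637 to 162300 in the second. Among genes dimmer than the median gene, the median log2 difference between NUP98-NSD1 and HoxA9 was -0.40, against -0.01 among the brighter genes. Both HoxA9+Meis1 against HoxA9 and MLL-ENL against NUP98-NSD1 stay within 1 set, where the medians were -0.05 against -0.01 and -0.16 against 0.04. Correlation between arrays over the genes followed the sets only in part. The median r between groups of 1 set was 0.909 (HoxA9 and HoxA9+Meis1) and 0.904 (MLL-ENL and NUP98-NSD1). Across the sets it was 0.876 (HoxA9 and NUP98-NSD1), 0.883 (HoxA9+Meis1 and NUP98-NSD1), 0.880 (HoxA9+Meis1 and MLL-ENL) and 0.915 (HoxA9 and MLL-ENL). Comparisons other than HoxA9+Meis1 against HoxA9 and MLL-ENL against NUP98-NSD1 cross the sets. In these no array of a group is in the set of the other, and set and group cannot be told apart. Of genes with at least 2 probe sets past the test, 21.3% (289 of 1357) had probe sets called in opposite directions between NUP98-NSD1 and HoxA9, 21.7% (334 of 1540) between NUP98-NSD1 and HoxA9+Meis1 and 23.1% (103 of 446) between MLL-ENL and HoxA9. Within a set the shares were 0.289% (1 of 346, the myelin gene Mbp) for HoxA9+Meis1 against HoxA9 and 1.48% (2 of 135) for MLL-ENL against NUP98-NSD1. The ratio of the 3 prime to the 5 prime Actb probe set, a sign of RNA quality, was 1.18 to 1.43 in the NUP98-NSD1 and MLL-ENL arrays and 1.09 to 1.17 in the others, and that of Gapdh was 0.849 to 0.932 against 0.777 to 0.836.

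**Figure D1:**
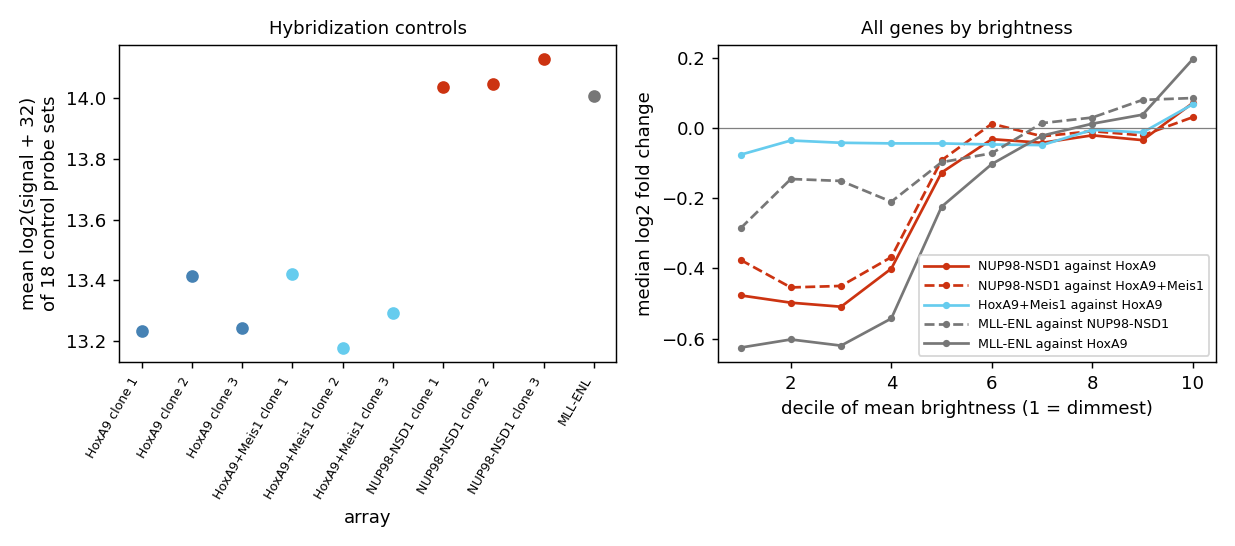
Left, the mean log2(signal + 32) of the 18 hybridization control probe sets, 1 point per array, which is 14.01 to 14.13 in the NUP98-NSD1 and MLL-ENL arrays and 13.18 to 13.42 in the others. Right, the median log2 fold change of the genes in each of 10 bins of mean brightness, 1 line per comparison, with the dim genes lowest in the comparisons that cross the array sets.

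The first question was whether NUP98-NSD1 cells express the Hox-A genes and Meis1. A Hoxa9 probe set that was near background in HoxA9 cells (signal 36.4 ± 12.9, SD, n = 3) and in HoxA9+Meis1 cells (27.2 ± 1.84, n = 3) reached 33622 ± 2870 in NUP98-NSD1 cells (n = 3) and 35209 in MLL-ENL. That is at least 83.7-fold higher than in HoxA9 (adjusted p = 2.1e-08). Where all arrays of the dimmer group lay below the filter level of 369, which was fixed as a percentile before the data were examined, a gene's fold is given as at least that against this level, since a fitted value would depend on the offset. The other Hoxa9 probe set read 43343 ± 16058 in HoxA9 cells and 94752 ± 7614 in HoxA9+Meis1 cells, where Hoxa9 was introduced, and 7379 ± 956 in NUP98-NSD1 cells, a log2 difference of -2.49 from HoxA9 (SE 0.22, adjusted p = 6.4e-05). Which part of the transcript each probe set reads was not used here. The mean of the Hoxa9 probe sets gave a log2 difference of 3.24 from HoxA9. That value averages a rise and a fall and depends on the offset, so it does not measure a net change of Hoxa9.

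Some probe sets of other Hox-A genes were also higher in NUP98-NSD1 cells than in HoxA9 cells. A Hoxa10 probe set rose from 349.7 ± 70.5 to 6909 ± 4024 (log2 4.06, SE 0.43, adjusted p = 1.5e-04, n = 3 per group), while a dimmer Hoxa10 probe set gave -0.50 and did not pass the test. Hoxa7 rose from 126 ± 17.3 to 1169 ± 762 (at least 2.45-fold, adjusted p = 0.00663, and at least 3.98-fold without NUP98-NSD1 clone 1). A Hoxa5 probe set rose from 368 ± 106 to 2499.9 ± 506 (log2 2.68, adjusted p = 0.00111), while the brighter Hoxa5 probe set that stands for the gene in the counts gave -0.12. As a whole the 7 measured Hox-A genes, 3 higher and 1 lower (3 and 1 adjusted over the list alone), did not pass limma's camera test against HoxA9 (adjusted p = 0.418). The higher ones were Hoxa10, Hoxa7 and Hoxa3. The Hoxa3 probe set that stands for the gene gave 0.98 (adjusted p = 0.0236) and another also rose (adjusted p = 0.0398). A further Hoxa3 probe set gave -0.96 and did not pass the test. Hoxa5 by its brighter probe set, Hoxa11 (-1.02) and Hoxa13 (0.14) did not pass either. The lower one was Hoxa9, represented by the probe set that read highest where Hoxa9 was introduced (-2.49). The list test thus leaves out the Hoxa9 and Hoxa5 probe sets that rose. The 7 genes passed with fry, which tests the list without comparing it with other genes (adjusted p = 0.00699, the lowest of 12 alternatives, which ended at 0.521).

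A Meis1 probe set was near background in HoxA9 cells (21.7 ± 5.72), read 606 ± 70.9 in HoxA9+Meis1 cells and 5379 ± 1054 in NUP98-NSD1 cells, and stood at 10159.6 in MLL-ENL. NUP98-NSD1 cells were thus at least 13.3-fold above HoxA9 cells (adjusted p = 3.8e-07). Whether this probe set reads the introduced Meis1 is not known here, so the value in HoxA9+Meis1 cells may leave it out. The probe set that stands for Meis1 in the counts had a higher mean over the arrays but gave -0.06. Nsd1, the mouse gene of the methyltransferase named in the fusion, fell from 3280.1 ± 989.7 in HoxA9 cells to 778 ± 167 in NUP98-NSD1 cells (brightest probe set, log2 -2.01, SE 0.38, adjusted p = 0.00334). Another Nsd1 probe set was at least 2.02-fold lower (adjusted p = 0.00524), and a dimmer one gave -0.32 and did not pass the test. Nup98 did not pass the test with its brightest probe set (log2 0.18, adjusted p = 0.414), while its other probe set fell by 0.56 against HoxA9 (adjusted p = 0.0148) and by 0.60 against HoxA9+Meis1 (adjusted p = 0.00978).

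**Figure D2:**
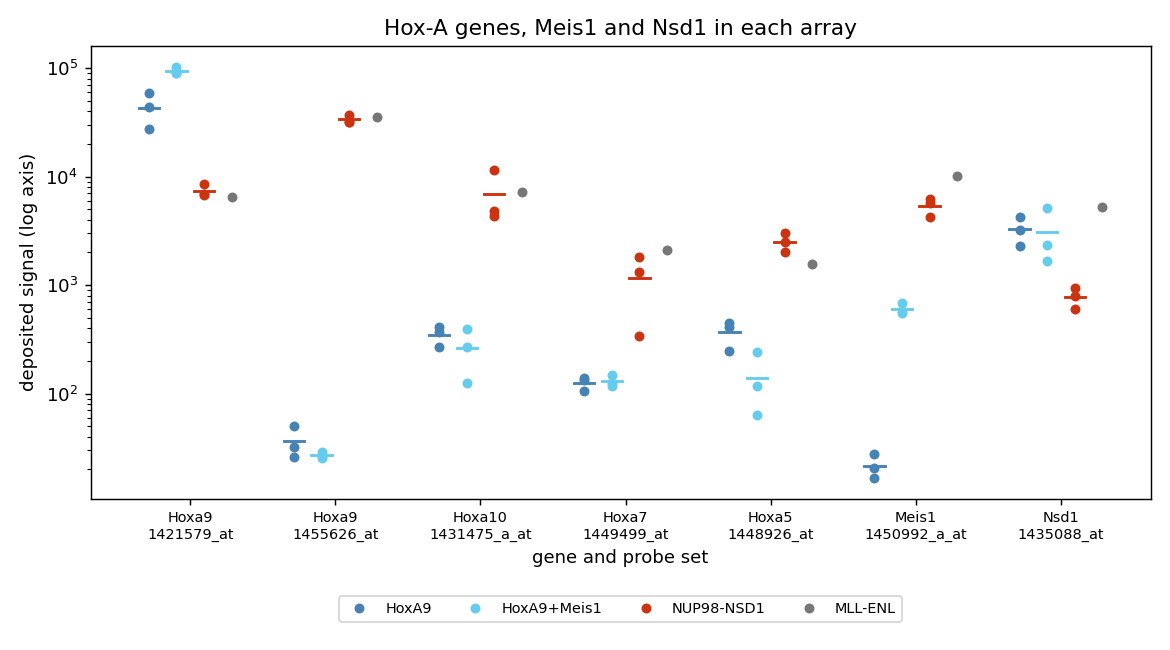
Deposited signal on a log axis of 7 probe sets of Hox-A genes, Meis1 and Nsd1, chosen after their values were seen, 1 point per array, with a line at each group's mean. The Hoxa9 probe set that was near background in HoxA9 cells averages 36.4 in HoxA9, 27.2 in HoxA9+Meis1 and 33622 in NUP98-NSD1 arrays, and reads 35209 in MLL-ENL.

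NUP98-NSD1 cells were higher than HoxA9 cells in the lists of secondary granule, mast cell, and stem and progenitor genes (adjusted p = 3.1e-06, 3.3e-08 and 0.00299). These calls were lost with an estimated correlation (adjusted p = 0.274, 0.274 and 0.310). S100a9, a subunit of the neutrophil protein calprotectin, rose 547-fold (log2 9.10, SE 1.05, adjusted p = 2.7e-04, n = 3 per group, and log2 8.14 without HoxA9 clone 2). Erg, a transcription factor of blood stem cells, rose at least 19.4-fold (adjusted p = 2.4e-08), and Cpa3, the mast cell carboxypeptidase, rose 83.6-fold (log2 6.39, SE 0.73, adjusted p = 2.4e-04). Among the genes that fell were Tgfbr3, the TGF-beta co-receptor betaglycan, by 36.2-fold (log2 -5.18, SE 0.53, adjusted p = 1.6e-04) and Sdc2, the heparan sulfate proteoglycan syndecan-2, by at least 11.7-fold (adjusted p = 1.1e-04).

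Of 17 measured genes of secondary granules and mature neutrophils, 12 rose against HoxA9, 0 fell and 5 did not pass the test (12 and 0 adjusted over the list alone). They included Camp, the antimicrobial peptide cathelicidin (at least 40.6-fold), and Ngp, a neutrophil granule protein (log2 6.45). Camp was high in NUP98-NSD1 clone 3 above all, and the bound was 62.3-fold, 62.7-fold and 17.1-fold without clones 1, 2 and 3. The list's median log2 difference was 2.35, or 2.27 with dim groups at the filter level (adjusted p = 3.1e-06, and adjusted p = 0.274 with an estimated correlation). Of 15 genes of mast cells, basophils and eosinophils, 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 4.11, or 3.01 with dim groups at that level (adjusted p = 3.3e-08, and adjusted p = 0.274 with an estimated correlation). Hdc, which makes histamine, rose 128-fold (log2 6.39 with an offset of 100, 6.36 without HoxA9 clone 2 and 7.75 without HoxA9 clone 3). Of 17 genes of primary granules, 12 rose and 1 fell (12 and 1 adjusted over the list alone), most by less: the median was 0.58 (adjusted p = 1.5e-07, and adjusted p = 0.244 with an estimated correlation). Nkg7, a protein of cytotoxic granules, rose at least 53.9-fold and the ficolin gene Fcnb by 4.91 on the log2 scale, while Clec5a, a myeloid lectin receptor, fell by 1.62. The call for primary granule genes was lost with quantile normalization (adjusted p = 0.0900, the highest of 12 alternatives, which began at 4.3e-09).

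Genes of stem and progenitor cells were higher as a list against HoxA9, with 9 of 19 up and 2 down (10 and 6 adjusted over the list alone; median 0.89, adjusted p = 0.00299, and adjusted p = 0.310 with an estimated correlation). The progenitor surface protein Cd34 rose by 6.18 (SE 0.86, adjusted p = 7.1e-04, and 5.55, 5.53 and 7.47 without HoxA9 clones 1, 2 and 3, of which clone 3 read 1845 against 97.8 and 93.9). Angpt1, a growth factor of blood vessels and marrow, rose by 5.35 (SE 0.59, adjusted p = 2.1e-04, and 4.65 without HoxA9 clone 1). Cd27, a TNF receptor family member, rose by 4.75 (SE 0.62, adjusted p = 5.0e-04, and 4.06 without HoxA9 clone 2). Of 17 leukaemia genes linked to Meis1 and HoxA9, 6 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.00662, and adjusted p = 0.244 with an estimated correlation). The receptor tyrosine kinase Flt3 rose by 1.57 (SE 0.28, adjusted p = 0.00284). Kit, the receptor for stem cell factor, differed by 0.49 and did not pass the test (SE 0.18, adjusted p = 0.0620).

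Of 35 myeloid transcription factors, 15 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.62, adjusted p = 6.0e-07, and adjusted p = 0.0634 with an estimated correlation), among them Ikzf2, a zinc finger factor of the Ikaros family (3.39), and Gata2 (2.51). Of 20 monocyte and macrophage genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.59, adjusted p = 0.0189, and adjusted p = 0.316 with an estimated correlation), with the lysosomal protease Ctss up by 4.54 and the transcription factor Klf4 at least 4.42-fold. Of 19 adhesion molecules, 8 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.75, adjusted p = 9.0e-04, and adjusted p = 0.244 with an estimated correlation), including the tetraspanin Cd9 (at least 9.58-fold), the integrin Itgb7 (log2 3.28) and Cd93 (2.82). Of 26 genes of H3K36 and MLL complex chromatin proteins, 8 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.00658, and adjusted p = 0.244 with an estimated correlation), Nsd1 among those that fell. Ribosomal protein genes were higher, 22 of 24 (22 adjusted over the list alone; median 0.62, adjusted p = 9.8e-16, and adjusted p = 0.244 with an estimated correlation), but not with quantile normalization (adjusted p = 0.918, the highest of 12 alternatives, which began at 9.4e-18). Rpl22 of the large ribosomal subunit rose by 0.83. These are among the brightest transcripts, and the hybridization controls were also higher in the NUP98-NSD1 arrays, by 0.79 (0.53 to 1.04 over the 18 probe sets).

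In all, 4483 of 14233 genes (31.5%) passed the test between NUP98-NSD1 and HoxA9, 1887 higher and 2596 lower, and 640 rose and 1171 fell at least 2-fold. The median over all genes was -0.14, and relative to it 766 genes rose and 1004 fell at least 2-fold. Genes whose 3 arrays of one group all lay above those of the other were 45.9% of all genes, where chance gives 10%. With arrays shifted to a common median, 2039 genes were higher and 1126 lower, so the more frequent direction depends on the scaling.

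**Figure D3:**
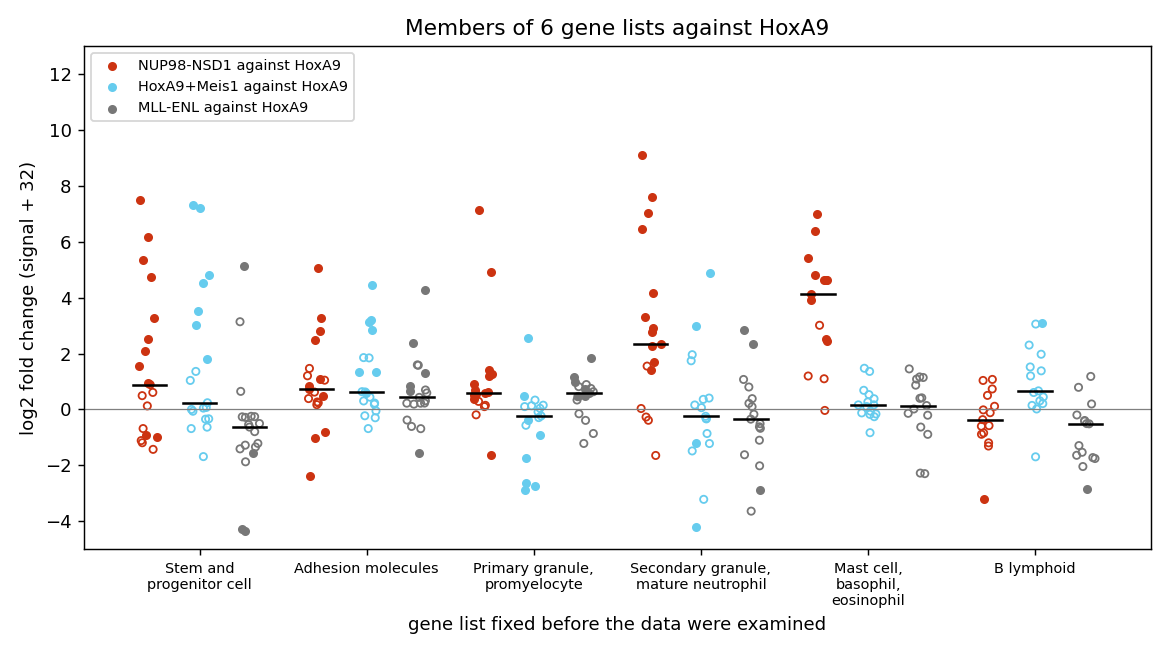
The log2 fold change of signal + 32 against HoxA9 (y) of each measured member of 6 gene lists (x), for NUP98-NSD1, HoxA9+Meis1 and MLL-ENL. Filled points passed the test, open points did not, and lines mark medians of fitted values, such as 4.11 for mast cell, basophil and eosinophil genes in NUP98-NSD1.

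Against HoxA9+Meis1, NUP98-NSD1 cells were higher in the lists of primary granule, secondary granule and mast cell genes (adjusted p = 1.5e-12, 2.5e-06 and 5.3e-07). These calls were lost with an estimated correlation (adjusted p = 0.244, 0.274 and 0.310). Hdc rose at least 49.3-fold (adjusted p = 1.3e-04, n = 3 per group). Elane, which encodes neutrophil elastase, rose 9.34-fold (log2 3.22, SE 0.19, adjusted p = 1.1e-05). Hpgd, which breaks down prostaglandins, fell 72.8-fold (log2 -6.19, SE 1.02, adjusted p = 0.00157, and -5.05 and -7.70 without NUP98-NSD1 clones 1 and 3), and H2-Ob, a chain of an MHC class II chaperone, fell at least 8.68-fold (adjusted p = 8.7e-04).

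Of 17 primary granule genes, 14 rose and 0 fell against HoxA9+Meis1 (15 and 0 adjusted over the list alone; median 0.76, adjusted p = 1.5e-12, and adjusted p = 0.244 with an estimated correlation). Besides Elane they included Nkg7 (4.60), Fcnb (4.81) and Ms4a3, a membrane protein of granulocyte precursors (3.04). Of 17 secondary granule and neutrophil genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 3.49, or 2.94 with dim groups at the filter level, adjusted p = 2.5e-06, and adjusted p = 0.274 with an estimated correlation), with Pglyrp1, which binds bacterial peptidoglycan, up by 5.27. Of 15 mast cell, basophil and eosinophil genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 4.24, or 3.17 with dim groups at that level, adjusted p = 5.3e-07, and adjusted p = 0.310 with an estimated correlation), with Cpa3 up by 6.22 (5.31 and 7.08 without HoxA9+Meis1 clones 2 and 3). Lrg1, a secreted glycoprotein of neutrophils, rose at least 16.5-fold (9.71-fold without NUP98-NSD1 clone 3). Of 35 myeloid transcription factors, 14 rose and 4 fell (18 and 4 adjusted over the list alone; median 0.41, adjusted p = 2.5e-05, and adjusted p = 0.0737 with an estimated correlation), with Ikzf2 up by 3.35 and Gfi1, a repressor needed for neutrophils, by 2.14. Of 25 cytokine and chemokine receptors, 9 rose and 7 fell (9 and 7 adjusted over the list alone; list adjusted p = 0.260), the risers including the G-CSF receptor Csf3r (2.59) and the GM-CSF receptor chain Csf2ra (2.45).

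Of 15 B lymphoid genes, 0 rose and 6 fell in NUP98-NSD1 against HoxA9+Meis1 (0 and 6 adjusted over the list alone; median -1.10, adjusted p = 0.0208, and adjusted p = 0.329 with an estimated correlation). Without HoxA9+Meis1 clone 2 the B lymphoid call was lost (adjusted p = 0.0544, the highest of 12 alternatives, which began at 0.00220). Of 13 dendritic cell and MHC class II genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone), but the list did not pass (median -0.69, adjusted p = 0.0629). It did with a common median (adjusted p = 0.0118), fry (0.0211), the clone number as a block (0.0486) and without HoxA9+Meis1 clone 3 (0.0114), 4 of 12 alternatives, which ended at 0.139. Siglech, a marker of plasmacytoid dendritic cells, fell by 2.95 (3.65 without NUP98-NSD1 clone 1 and 3.60 without HoxA9+Meis1 clone 3) and the integrin Itgax by 2.80 (3.43 without HoxA9+Meis1 clone 3). Stem and progenitor genes went both ways, 3 up and 4 down of 19 (4 and 5 adjusted over the list alone; median -0.48, adjusted p = 0.965). Eng, a TGF-beta co-receptor, rose by 3.61 and Tal1, a stem cell and erythroid factor, by 2.30, while Flt3 fell by 3.24. Cd34 differed by -1.12 and did not pass (SE 0.86, adjusted p = 0.343). Of 19 adhesion molecules, 4 rose and 7 fell (4 and 9 adjusted over the list alone; adjusted p = 0.312, and 0.0461 with fry, the lowest of 12 alternatives, which ended at 0.524).

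Of 26 genes of H3K36 and MLL complex chromatin proteins, 10 rose and 2 fell against HoxA9+Meis1 (11 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.00438, and adjusted p = 0.244 with an estimated correlation), such as the demethylase Kdm4c (1.10). Ribosomal protein genes were higher, 18 of 24 (18 adjusted over the list alone; median 0.44, adjusted p = 1.4e-10, and adjusted p = 0.274 with an estimated correlation), but with quantile normalization the list turned to the other direction (adjusted p = 0.978, the highest of 12 alternatives, which began at 1.6e-12). The hybridization controls were higher in the NUP98-NSD1 arrays by 0.77. In all, 4608 genes (32.4%) passed the test, 2016 higher and 2592 lower, and 746 rose and 1132 fell at least 2-fold, or 883 and 955 relative to the median over all genes of -0.13. Groups lay apart in 46.7% of all genes, where chance gives 10%, and with arrays shifted to a common median 2029 genes were higher and 1290 lower.

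HoxA9+Meis1 cells were higher than HoxA9 cells in the lists of adhesion and of stem and progenitor genes (adjusted p = 4.0e-07 and 1.3e-04) and lower in that of primary granule genes (0.0176). These calls were lost with an estimated correlation (adjusted p = 0.206, 0.250 and 0.536). The Hoxa9 probe set that read highest where Hoxa9 was introduced was also higher in HoxA9+Meis1 cells (log2 1.20, SE 0.22, adjusted p = 0.00976). A higher Hoxa9 level and the added Meis1 cannot be told apart in this comparison. Cd34 rose 157-fold (log2 7.30, SE 0.86, adjusted p = 7.2e-04, n = 3 per group, and 6.66, 6.64 and 8.59 without HoxA9 clones 1, 2 and 3). Erg rose at least 15.7-fold (adjusted p = 3.6e-08) and Flt3 28.0-fold (log2 4.81, SE 0.28, adjusted p = 1.4e-05). Gpr171, a G protein-coupled receptor, rose at least 19.6-fold (adjusted p = 1.9e-05). Mreg, a protein of organelle transport, fell at least 19.9-fold (adjusted p = 0.00103, and 44.1-fold and 13.2-fold without HoxA9 clones 1 and 3) and the amino acid transporter Slc36a4 at least 18.7-fold (adjusted p = 3.2e-05).

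Of 19 adhesion molecules, 7 rose and 0 fell in HoxA9+Meis1 against HoxA9 (11 and 0 adjusted over the list alone; median 0.63, adjusted p = 4.0e-07, and adjusted p = 0.206 with an estimated correlation), among them Itgb7 (4.46), Itgax (3.19, and 3.82 without HoxA9+Meis1 clone 3) and Cd93 (3.14). Of 17 leukaemia genes linked to Meis1 and HoxA9, 6 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.54, adjusted p = 4.9e-06, and adjusted p = 0.169 with an estimated correlation). Of 19 stem and progenitor genes, 7 rose and 0 fell (9 and 2 adjusted over the list alone; median 0.24, adjusted p = 1.3e-04, and adjusted p = 0.250 with an estimated correlation), Cd27 by 4.53 (3.85 without HoxA9 clone 2 and 5.13 without HoxA9+Meis1 clone 3). Of 15 B lymphoid genes, 1 rose, Il7r, the interleukin-7 receptor, by 3.08, or 3.84 without HoxA9+Meis1 clone 3 (3 up and 1 down adjusted over the list alone), and the list was higher (median 0.67, adjusted p = 0.00664, and adjusted p = 0.274 with an estimated correlation). Of 13 dendritic cell and MHC class II genes, 3 rose and 0 fell (4 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.0284, and adjusted p = 0.457 with an estimated correlation), with Tcf4, a factor of plasmacytoid dendritic cells, up by 1.59. Of 20 monocyte and macrophage genes, 5 rose and 1 fell (6 and 4 adjusted over the list alone; median 0.41, adjusted p = 0.0307, and adjusted p = 0.369 with an estimated correlation), with Ctss up by 4.55 and the chemokine Ccl3 by 2.23. The dendritic cell call was lost without HoxA9 clone 1 (adjusted p = 0.0698), HoxA9+Meis1 clone 1 (0.0673) or HoxA9+Meis1 clone 2 (0.0836, the highest of 12 alternatives, which began at 0.00254). The monocyte call was lost without HoxA9 clone 1 (adjusted p = 0.116, the highest of 12, which began at 0.00532), without HoxA9+Meis1 clone 2 (0.0507) and with quantile normalization (0.0536).

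Of 17 primary granule genes, 2 rose and 6 fell in HoxA9+Meis1 against HoxA9 (2 and 8 adjusted over the list alone; median -0.23, adjusted p = 0.0176, and adjusted p = 0.536 with an estimated correlation). The falls included Igsf6, a membrane protein of myeloid cells (-2.90), Ms4a3 (-2.75) and Elane (-2.64), and Nkg7 rose at least 2.22-fold. Secondary granule genes went both ways, 2 up and 2 down of 17 (3 and 2 adjusted over the list alone; adjusted p = 0.977), with the collagenase Mmp8 up by 3.00 (2.41 without HoxA9+Meis1 clone 2) while Csf3r fell. None of the 15 mast cell, basophil and eosinophil genes passed the test (0 adjusted over the list alone; limma list test adjusted p = 0.414). Myeloid transcription factors also went both ways, 5 up and 4 down of 35 (8 and 6 adjusted over the list alone; adjusted p = 0.401), with Gfi1, Cebpb and Cebpd lower (-1.73, -1.22 and -1.19). Of 25 cytokine and chemokine receptors, 3 rose and 4 fell (4 and 5 adjusted over the list alone; median 0.07, adjusted p = 0.571). Those that rose included Flt3 and Il7r, and those that fell Csf2ra (-3.07), the interferon gamma receptor chain Ifngr1 (-1.55) and Csf3r (-1.19). Ribosomal protein genes moved little, 1 of 24 up (0 adjusted over the list alone; median 0.17), and the list's call (adjusted p = 3.1e-06, and adjusted p = 0.407 with an estimated correlation) was lost with quantile normalization (0.727, the highest of 12 alternatives, which began at 5.1e-07) and with cyclic loess (0.0940).

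In all, 1376 genes (9.67%) passed the test between HoxA9+Meis1 and HoxA9, 656 higher and 720 lower, and 288 rose and 306 fell at least 2-fold. Groups lay apart in 31.2% of all genes, where chance gives 10%. The count was 770 without HoxA9 clone 2, 911 without HoxA9 clone 3, 788 without HoxA9+Meis1 clone 1 and 748 without HoxA9+Meis1 clone 2, and it was 759 with arrays shifted to a common median, where the more frequent direction turned (446 higher and 313 lower), and 773 with eBayes without a trend.

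Many genes differed from HoxA9 the same way in NUP98-NSD1 and HoxA9+Meis1. The genes higher in both were 352, and those lower in both were 243. Independent lists of that length would overlap in 87.0 and 131, which leaves out the shared HoxA9 arrays. Simulated groups without any difference that share them overlapped in 0 and 0, which leaves out the differences. Erg, Cd34, Cd27, Ctss, Itgb7 and Cd93 rose in both, and Tgfbr3, Slc36a4 and Slfn4 fell in both. A further 71 genes were higher in NUP98-NSD1 and lower in HoxA9+Meis1, and 28 went the opposite way (95.5 and 119.7 for independent lists). Across genes, which are not independent replicates, the 2 sets of log2 differences correlated with r = 0.41, but both use the same HoxA9 arrays, and simulated groups without any difference gave a mean of 0.50. Their covariance, 0.264, was above the simulated 0.0680, whose highest value was 0.0751. The simulated noise followed each gene's own spread and left out correlation between genes, so the simulated range may be too narrow. The 595 genes called the same way became 323 without HoxA9 clone 2, 390 without HoxA9 clone 3, 370 without HoxA9+Meis1 clone 1, 350 without HoxA9+Meis1 clone 2 and 346 with arrays shifted to a common median.

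The MLL-ENL array was lower than NUP98-NSD1 in the lists of secondary granule, mast cell, and stem and progenitor genes. Their medians lay below those of all 10000 random lists of like brightness. Leukaemia genes linked to Meis1 and HoxA9 (-0.95, or -0.22 with dim groups at the filter level) also did. Glycolysis genes (-0.32) and myeloid transcription factors (-0.29) did as well. Random lists leave out correlation between members. It was estimated at 0.32 (secondary granule), 0.57 (mast cell) and 0.14 (stem and progenitor). S100a9 was at least 517-fold lower (adjusted p = 0.00451, 1 array against 3) and Cpa3 155-fold (log2 -7.28, SE 1.03, adjusted p = 0.00489). Hmgn1, a nucleosome-binding protein, was 146-fold lower (log2 -7.19, SE 1.01, adjusted p = 0.00469). Higher in MLL-ENL were Sgip1, an endocytic adaptor (log2 4.35, SE 0.71, adjusted p = 0.00962), the prostaglandin reductase Ptgr1 (4.31, SE 0.65, adjusted p = 0.00667, and 4.91 without NUP98-NSD1 clone 3) and Slc36a4 (4.04, SE 0.66, adjusted p = 0.00901).

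Of 15 mast cell, basophil and eosinophil genes, 0 were higher and 8 lower in MLL-ENL than in NUP98-NSD1 (0 and 11 adjusted over the list alone), with a median of -3.96 (-3.19 with dim groups at the filter level), below all random lists. Of 17 secondary granule and neutrophil genes, 0 were higher and 5 lower (0 and 11 adjusted over the list alone; median -2.70, or -1.47 with dim groups at that level, below all random lists), such as Ngp (-6.95). Of 19 stem and progenitor genes, 0 were higher and 8 lower (0 and 14 adjusted over the list alone; median -2.35, or -2.07 with dim groups at that level, below all random lists). Of 20 monocyte and macrophage genes, 2 were higher and 2 lower (3 and 2 adjusted over the list alone), and the median of 0.38 lay above 99.96% of random lists. The 7 Hox-A genes had 0 calls (0 adjusted over the list alone; limma), with a median of -0.18 at percentile 30.0. Hoxa9 differed by -0.18 (SE 0.32, adjusted p = 0.812) and Hoxa10 by 0.21 (SE 0.62, adjusted p = 0.894), and neither passed the test. Primary granule genes had a median of -0.05 (percentile 2.80), with 0 of 17 higher and 3 lower (1 and 4 adjusted over the list alone).

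In all, 683 genes (4.80%) passed the test between MLL-ENL and NUP98-NSD1, 259 higher and 424 lower, and 104 were higher and 356 lower by at least 2-fold. All 683 lay outside the range of the NUP98-NSD1 arrays, as did 58.6% of all genes, where chance gives 50%. MLL-ENL has 1 array, so its spread is taken from the other groups and nothing checks it. The count was 430 without NUP98-NSD1 clone 1, 371 without clone 2 and 1442 without clone 3.

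Against HoxA9, the MLL-ENL array was higher in the lists of monocyte and ribosomal protein genes, whose medians lay above those of all 10000 random lists. Random lists leave out the correlation between members, estimated at 0.080 for monocyte and 0.494 for ribosomal protein genes. These medians and random lists used values as deposited only. In NUP98-NSD1 against HoxA9, which also crosses the array sets, the camera call for ribosomal protein genes was lost with quantile normalization (adjusted p = 0.918). Erg was at least 3.76-fold higher (adjusted p = 1.7e-05, 1 array against 3), Wfdc17, a secreted protease inhibitor, 53.6-fold (log2 5.74, SE 0.69, adjusted p = 0.00139, and 6.37 without HoxA9 clone 3) and Ctss 29.0-fold (log2 4.86, SE 0.46, adjusted p = 5.8e-04). Hoxa7 was at least 5.30-fold higher (adjusted p = 0.0138), and the Meis1 probe set near background in HoxA9 cells read 10159.6 against 21.7. Rgs8, a regulator of G protein signalling, was at least 4.36-fold lower (adjusted p = 9.2e-04), and Tal1 at least 9.12-fold (adjusted p = 0.00540).

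Of 20 monocyte and macrophage genes, 6 were higher and 1 lower in MLL-ENL than in HoxA9 (8 and 2 adjusted over the list alone), and their median of 0.88 lay above all random lists. Of 17 primary granule genes, 7 were higher and 0 lower (11 and 0 adjusted over the list alone; median 0.60, percentile 99.96). Of 24 ribosomal protein genes, 18 were higher and 0 lower (20 and 0 adjusted over the list alone; median 0.62, above all random lists). The hybridization controls were higher in the MLL-ENL array by 0.72. Of 35 myeloid transcription factors, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; median 0.32, percentile 99.95). Of 19 adhesion molecules, 5 were higher and 1 lower (6 and 2 adjusted over the list alone; median 0.43, percentile 99.92). None of the 15 mast cell, basophil and eosinophil genes passed the limma test (0 adjusted over the list alone; median 0.14, percentile 98.58). Of 17 secondary granule genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone; median -0.35, percentile 7.24), and of 19 stem and progenitor genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone; median -0.63, percentile 1.18).

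In all, 2083 genes (14.6%) passed the test between MLL-ENL and HoxA9, 813 higher and 1270 lower, and 232 were higher and 884 lower by at least 2-fold, or 328 and 832 relative to the median over all genes of -0.15. All 2083 lay outside the range of the HoxA9 arrays, as did 74.8% of all genes, where chance gives 50%. The count was 1342 without HoxA9 clone 2 and 1314 with quantile normalization, and with arrays shifted to a common median 1851 genes were higher and 494 lower.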

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

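Of the tests in this part, those on probe sets called in opposite directions were chosen after the result was seen. The splits of the arrays were planned.

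The hybridization control probe sets, which enter none of the gene comparisons, differed between NUP98-NSD1 and HoxA9 arrays by a median of 0.79 on the log2 scale. Of the probe sets with no single gene name, 1408 of 5486 were called between NUP98-NSD1 and HoxA9, and they are not described by gene.

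The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 4483 genes for NUP98-NSD1 against HoxA9, 4608 for NUP98-NSD1 against HoxA9+Meis1 and 1376 for HoxA9+Meis1 against HoxA9, and the highest of the other splits gave 1, 1 and 2. In each comparison 1 of the 10 splits, the real one, gave as many genes. Every other split mixes arrays of both groups, which puts a real difference into the spread and leaves few calls whatever its cause. In the NUP98-NSD1 comparisons the splits therefore cannot tell oncogene from array set.

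Probe sets of 1 gene were called in opposite directions in 21.3% of genes with at least 2 called between NUP98-NSD1 and HoxA9, and in 0.289% between HoxA9+Meis1 and HoxA9. A difference that depends only on brightness is argued against as far as cyclic loess removes it, since the share was 21.7% after that step. How much of the shift of dim genes cyclic loess left was not measured. Another difference in how the arrays were made is a candidate explanation: the gap between such probe sets in MLL-ENL against HoxA9+Meis1, which compares other arrays across the sets, was 80.9% of that in NUP98-NSD1 against HoxA9. Lower RNA integrity in the NUP98-NSD1 and MLL-ENL cultures stays open. The ratio of the 3 prime to the 5 prime Actb probe set was 1.18 to 1.43 there and 1.09 to 1.17 in the others, and that of Gapdh 0.849 to 0.932 against 0.777 to 0.836. Both ratios move with the groups, but the lowest Actb ratio, 1.18, was above the highest of the others by less than the spread within groups. Array set and oncogene cannot be told apart, and a biological explanation, such as transcripts that end elsewhere in the cells with fusion oncogenes, was not tested.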

How the results depend on the processing

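Cyclic loess and the count over genes with at least 2 called probe sets were chosen after the data were seen. The counts of called genes stayed within 1.5 times under offsets of 1 and 100, no filter, the 60th percentile filter, the mean of probe sets, suffix probe sets left out, robust eBayes, the smaller fits and cyclic loess (4276, 4487, 1378, 634 and 1558, in the order NUP98-NSD1 against HoxA9, against HoxA9+Meis1, HoxA9+Meis1 against HoxA9, MLL-ENL against NUP98-NSD1, MLL-ENL against HoxA9). With the clone number as a block they were 4104, 4230, 1204, 463 and 1642. Residuals of arrays with the same clone number correlated with r of -0.070 to 0.038 over 9 pairs, and with different numbers -0.064 to 0.070 over 18, so the numbers do not pair the arrays.

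Counting every probe set gave 8979, 9575, 2131, 1231 and 4477 of 30945, since more are tested. Genes with at least 2 called probe sets and none the other way were 1068, 1206, 345, 133 and 343, since fewer genes can qualify. A common median left 759 for HoxA9+Meis1 against HoxA9 and 346 genes of shared direction, eBayes without a trend left 773 for the former, and quantile normalization left 1314 for MLL-ENL against HoxA9. The cause was not tested. Leaving out 1 clone gave 3095 to 4533, 3249 to 4358, 748 to 1205, 371 to 1442 and 1342 to 1517, and 323 to 818 for the shared direction. The share of called genes that were lower went from 57.9% to 35.6% with a common median for NUP98-NSD1 against HoxA9, from 56.25% to 38.9% against HoxA9+Meis1, from 52.3% to 41.2% for HoxA9+Meis1 against HoxA9, from 62.1% to 51.0% for MLL-ENL against NUP98-NSD1 and from 61.0% to 21.1% for MLL-ENL against HoxA9.

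All 36 list calls were lost with an estimated correlation, which left 0. Other settings called 29 (quantile), 33 (cyclic loess), 36 (no filter), 39 (common median, and block) and 45 (fry) lists, and leaving out 1 clone 31 to 38. Ribosomal protein genes turned in NUP98-NSD1 against HoxA9+Meis1 with quantile normalization (adjusted p = 0.978). The cause was not tested.

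Of 374 gene and comparison pairs that could be named, 343 passed the test, and 224 of these kept direction and call under every alternative run. In 107 the call was lost at least once, and 19 reversed in at least 1, each time because another probe set or an average stood for the gene. Values of these 19 follow, with those of 6 pairs that were not called but turned (Meis1 and Hoxa5). For NUP98-NSD1 against HoxA9, log2 values without suffix probe sets were -0.50 (Hoxa10), 0.026 (Cd8a), 0.18 (Ccne1), 0.17 (Phc2), -0.47 (Rps20), -1.32 (Rpl35) and 2.68 (Hoxa5), with the mean of probe sets 3.24 (Hoxa9), -0.051 (Slbp), -0.57 (Tpx2), 2.13 (Meis1) and 1.28 (Hoxa5), and with the 60th percentile filter 6.64 (Meis1). Against HoxA9+Meis1 they were -0.43 (Hoxa10), 0.072 (E2f1), -1.07 (Rps20), -0.20 (Rps24) and 3.99 (Hoxa5) without suffix probe sets, and 2.73 (Hoxa9), 0.043 (Msi2), -0.56 (Tpx2), -0.12 (Rps20) and 1.91 (Hoxa5) with the mean. For HoxA9+Meis1 against HoxA9, Meis1 gave 3.57 with the 60th percentile filter and 1.07 with the mean. For MLL-ENL against HoxA9 they were -0.021 (Hoxa10), 0.57 (Slc2a3) and 2.04 (Hoxa5) without suffix probe sets, 3.18 (Hoxa9) and 2.32 (Meis1) with the mean, and 7.57 (Meis1) with the filter. These are fitted values, also where all arrays of the dimmer group lay below the filter level. Against that level the log2 differences were at least 3.73, 0.66 and 4.67 for Meis1 in NUP98-NSD1, HoxA9+Meis1 and MLL-ENL against HoxA9, and at least 2.64 for Hoxa5 in NUP98-NSD1 against HoxA9+Meis1. Fitted values of genes near background depend on the offset: with 1 and 100, the probe sets near background in HoxA9 gave 9.87 and 7.95 (Hoxa9) and 7.90 and 5.47 (Meis1) for NUP98-NSD1 against HoxA9. Signal over background limits the dim genes, whose median moved most between the array sets.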

Other observations

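The tests of explanations in this part were all chosen after the result was seen. Of 11 measured genes of the Hox-B, Hox-C and Hox-D clusters, 4 rose and 0 fell in NUP98-NSD1 against HoxA9 and against HoxA9+Meis1 (4 and 0 adjusted over the list alone). Hoxb5 rose at least 4.13-fold in both (adjusted p = 2.4e-04), Hoxb2 by 2.58 and 3.91 on the log2 scale (4.58 without HoxA9+Meis1 clone 2), Hoxb3 by 1.53 and 2.82 and Hoxb4 by 0.71 and 1.11, while Hoxb7 differed by -0.55 and -0.42 and did not pass. The list did not pass (adjusted p = 0.245 and 0.0633). Against HoxA9 it passed with fry (9.5e-04, the lowest of 12 alternatives, which ended at 0.631), and against HoxA9+Meis1 in 4 of 12, with quantile normalization (0.0461), cyclic loess (0.0421), fry (9.5e-04) and without HoxA9+Meis1 clone 2 (0.0314), over a range that ended at 0.341. Its median against HoxA9 was -0.45 and its mean 0.47. In MLL-ENL 0 of the 11 were higher and 4 lower than in NUP98-NSD1 (0 and 6 adjusted over the list alone; median -1.10, percentile 0.61 of random lists, or -0.38 with dim groups at the filter level).

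Immediate early and heat shock genes, which respond to growth signals and stress, were higher in NUP98-NSD1 than in HoxA9, 11 of 24 up and 4 down (12 and 4 adjusted over the list alone; median 0.72, adjusted p = 3.4e-04, and adjusted p = 0.244 with an estimated correlation), with Fos up by 2.35 and the phosphatase Dusp1 by 1.74. In HoxA9+Meis1 against HoxA9, 6 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.36, adjusted p = 2.3e-04, and adjusted p = 0.244 with an estimated correlation), with Zfp36, which destabilizes cytokine transcripts, up by 2.21, Jun by 1.57 while Gadd45b fell by 2.15. Of 17 cyclin-dependent kinase inhibitors and apoptosis genes, 7 rose and 4 fell in NUP98-NSD1 against HoxA9 (8 and 4 adjusted over the list alone; median 0.21, adjusted p = 0.0239, and adjusted p = 0.244 with an estimated correlation). The inhibitor Cdkn2a rose by 1.48 and the death gene Bcl2l11 by 1.29, while the inhibitor Cdkn2c fell by 1.30. The call was lost with cyclic loess (adjusted p = 0.0643, the highest of 12 alternatives, which began at 9.5e-04). In HoxA9+Meis1 against HoxA9, 3 of the 17 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.244 with an estimated correlation), with the survival gene Bcl2 up by 1.35. Replication genes rose there in 3 of 23 and fell in 0 (5 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.00158, and adjusted p = 0.244 with an estimated correlation), with the helicase subunit Mcm2 up by 0.59. Interferon response genes were lower there, 0 of 23 up and 5 down (0 and 6 adjusted over the list alone; median -0.22, adjusted p = 0.0250, and adjusted p = 0.538 with an estimated correlation), with Oas1a, an antiviral enzyme, at -3.13. That call was lost without HoxA9 clone 3 (adjusted p = 0.233, the highest of 12 alternatives, which began at 0.00292), without HoxA9+Meis1 clone 3 (0.109) or with fry (0.0885).

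Some list calls rested on single arrays, the scaling or the list test. In NUP98-NSD1 against HoxA9+Meis1, interferon response genes were higher, 5 of 23 up and 2 down (5 and 2 adjusted over the list alone; adjusted p = 0.0206, and adjusted p = 0.531 with an estimated correlation), with Oas1a up by 2.09, but not without HoxA9+Meis1 clone 3 (0.0530) or NUP98-NSD1 clone 3 (0.0865), nor with fry (0.115), over a range of 0.00954 to 0.115. Cholesterol synthesis genes were higher, 7 of 20 up and 2 down (8 and 2 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.556 with an estimated correlation), with Dhcr7 up by 1.43, but not without HoxA9+Meis1 clone 2 (0.0788) or NUP98-NSD1 clone 3 (0.104), nor with fry (0.0615), over a range of 0.00614 to 0.104. Glycolysis genes were higher in NUP98-NSD1 than in HoxA9, 6 of 19 up and 1 down (6 and 1 adjusted over the list alone; adjusted p = 0.00515, and adjusted p = 0.506 with an estimated correlation), with the aldolase Aldoc up by 2.68, but not with quantile normalization (0.596), cyclic loess (0.254) or fry (0.0633), over a range of 3.9e-04 to 0.596. Against HoxA9+Meis1 they were 5 up and 0 down (5 and 0 adjusted over the list alone; adjusted p = 0.0482, and adjusted p = 0.602 with an estimated correlation), and 7 of 12 alternatives lost that call, over a range of 0.00606 to 0.596. Mitosis genes were higher against HoxA9, 7 of 23 up and 2 down (8 and 3 adjusted over the list alone; adjusted p = 0.0310, and adjusted p = 0.624 with an estimated correlation), but not without HoxA9 clone 1 (0.109) or NUP98-NSD1 clone 3 (0.198), nor with quantile normalization (0.0797), cyclic loess (0.178) or fry (0.178), over a range of 0.00591 to 0.198.

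Markers of 4 other lineages did not pass limma's camera test in NUP98-NSD1 against HoxA9: erythroid (2 up and 1 down of 15, and 2 and 1 adjusted over the list alone; adjusted p = 0.635), megakaryocyte (2 and 2 of 11, and 2 and 3; 0.473), T and NK cells (1 and 1 of 9, and 1 and 0; 0.937), and stromal and endothelial cells (2 and 5 of 14, and 3 and 8; 0.228). Of these, stromal and endothelial genes passed with fry (0.00632, the lowest of 12 alternatives, which ended at 0.453). A probe set of Xist, the transcript of the inactive X chromosome, read 2336 in HoxA9 clone 1 against 24495 and 30151 in the other HoxA9 clones, and no Y-linked probe set stood out in that clone. The same Xist probe set read 5694 to 9694 in the HoxA9+Meis1 clones, 24613 to 40564 in the NUP98-NSD1 clones and 16134 in MLL-ENL. No comparison of groups passed the test for it.

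Nsd1 was lower in NUP98-NSD1 than in HoxA9 cells (log2 difference -2.01). A brightness-dependent difference between the arrays is argued against as far as cyclic loess removes it, since Nsd1 was still at -1.90 after that step (SE 0.38, adjusted p = 0.00497). Another difference between the array sets stays open: MLL-ENL, in the same set, was 2.72 above NUP98-NSD1, but that is 1 array, and the call was lost without NUP98-NSD1 clone 2 (2.55). The mean of probe sets also ended that call (1.97). Fewer transcripts of the mouse gene in cells with the fusion remain possible and were not tested otherwise.

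Secondary granule and mast cell genes were higher in NUP98-NSD1 than in HoxA9 cells (medians 2.35 and 4.11, or 2.27 and 3.01 with dim groups at the filter level; adjusted p = 3.1e-06 and 3.3e-08, and adjusted p = 0.274 for both with an estimated correlation). A brightness-dependent difference is argued against as far as cyclic loess removes it, since the lower of the medians was 2.64 after that step. A share of more mature cells in the NUP98-NSD1 cultures stays open. It was predicted to put all 32 genes of both lists above all HoxA9 arrays in each clone, and 26 were in each. The lists were already called higher, so this count cannot decide it. Higher expression of those genes in every cell is also possible, and arrays of whole cultures cannot tell these explanations apart. The clone medians were 1.85, 1.89 and 3.27 for secondary granule genes and 4.92, 4.68 and 2.33 for mast cell genes, in the order of clones 1, 2 and 3. Clone 3 was thus highest for the former and lowest for the latter, so the lists did not rise in step.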
